A study of Mus musculus with 23 samples.

How the data were processed

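The series holds RNA sequencing of testis from male mice of 3 inbred strains, C57BL/6J, CAST/EiJ and NZO/HlLtJ, kept from 6 to 16 weeks of age on a control diet with 10% fat or a diet rich in fat and sugar with 44% fat, each with fiber per the labels. Each of the 23 libraries came from a separate testis sample. Per the labels, polyA RNA libraries were made with the KAPA mRNA HyperPrep kit and read as 100 bp pairs on a NovaSeq, with a target of 30 M read pairs (M, 1e+06). Spike-in RNA was added before library construction, but the count table lists 0 spike-in transcripts, so no scaling by spike-ins was possible.

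The deposited count table gives estimated counts per gene for 28861 genes: 22.6% of its values are not whole numbers, and library totals were not equalised. A second deposited table gives log2 values from a variance-stabilising transformation by the authors, between 7.67 and 19.3. The submitters' processing notes name the GRCm38 build and DESeq2. The aligner, the counting tool, the annotation release and any handling of strain variants are not given in the sources used here. Every gene in the count table had a count above 0 in at least 12 of the 23 libraries, so genes seen in fewer libraries had been removed before deposit, and a gene expressed in 1 strain only can be missing. Gene starts and ends came from the annotation table by the authors. Of its genes 99.3% were found in GENCODE M21, where 87.4% of starts were equal.

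Estimated counts were rounded to whole numbers. Genes with low counts were removed with filterByExpr on the 6 groups, which left 22873 genes. Tests used the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 with TMM scaling, 1 mean per group and all 23 libraries in 1 fit. Benjamini-Hochberg adjustment was applied over all genes tested, with a threshold of 0.05 and no limit on the fold. Adjusted p values of single genes below come from this test unless another tool is named. Comparisons were 44% fat minus 10% fat in each strain and averaged over strains, the difference of the diet effect between strains (all strains at once, and each pair), and each pair of strains averaged over diets. Values are TMM-scaled counts per 1e+06 counts (CPM), given as mean ± SD over libraries, and log2 fold changes carry the standard error (SE) of the fit.

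Gene lists (34 lists with 624 tested members, of the kinds testis cell type, neighbouring tissue, sample handling, pathway and sex chromosome) were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2. Adjustment was over the 34 lists of a comparison. Beside it stand camera with an estimated correlation, and fry, which asks whether the genes of a list move on balance one way and compares the list with no other genes. The count of changed members of a list is given over all genes tested and, where it differs, adjusted over the list alone. The named genes followed a rule. In diet comparisons these were all genes past the threshold up to 10 per direction, and the 5 with the smallest p where fewer than 5 passed, with an official symbol and a mean of at least 1 CPM. In strain comparisons these were the 8 largest changes per direction with at least 5 CPM. To these were added up to 3 changed members per list, Nnt in every comparison, and Star, Cyp17a1 and Insl3 in the diet comparisons. The groups, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. Genes named outside the rule are said to be chosen later. Some genes that the rule names are not reported here.

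Where a strain had 0 counts of a gene, the fold is given as a bound computed from 3 counts over the group, and with 1 to 3 counts as a ratio with an exact 95% interval. Such intervals and bounds cover counting error only, since PCR copies are not independent molecules. Totals per library ran from 21.9 to 78.7 M estimated counts, with a median of 35.1 M. Over 33 pairs of replicates, the chi-square of counts divided by its degrees of freedom lay between 3.47 and 19.2, so replicates differed by more than counting error. Counts were also simulated with the same spread. A fold of 1.25 in 67 genes was recovered in 50.7% of them for diet in C57BL/6J, 38.8% in CAST/EiJ and 62.7% in NZO/HlLtJ. A fold of 1.5 was recovered in 86.6%, 77.6% and 83.6%, and a fold of 2 in 100%, 93.9% and 98.5%. Altered genes had at least 1 CPM in every strain. Genes of all these folds, and others altered in all strains, were present together. Many true changes loosen the adjustment, so recovery can be lower where few genes change. A simulated list of 25 genes raised by a fold of 1.15 was called by camera at both correlations and by fry, while 0 of 33 unaltered lists were called. Simulated genes were drawn independently of each other, so this says nothing about list calls where genes move together.

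Sample titles carry ID numbers that fall into 3 runs. No label says that the runs are batches, so the run entered only as an alternative with a covariate. The NZO/HlLtJ 10% fat group has no library of run 2 and the NZO/HlLtJ 44% fat group none of run 3. Labels give no replicate numbers, so replicates are numbered here in the order of the series. Alternatives were other size factors, other filters on low counts, the run as a covariate, fits on the 2 groups compared, DESeq2 1.42.0, limma voom with sample weights, limma on the deposited log2 values, a 2-fold limit, 1 diet only, other list tests, and leaving out each library. Leaving out 2 libraries with epididymal transcripts, and 2 NZO/HlLtJ libraries apart on the fourth principal component, was chosen after seeing the data. Female samples are named in the series text but not used here.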

Results

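Testis RNA was sequenced from 23 male mice in 6 groups. C57BL/6J, the strain of the reference genome, contributed 4 libraries on 10% fat and 4 on 44% fat. CAST/EiJ, a wild-derived strain, contributed 3 and 4. NZO/HlLtJ, an inbred strain prone to obesity and diabetes, contributed 4 and 4. Library totals were 21.9 to 38.4 M (1e+06) estimated counts in C57BL/6J, 33 to 78.7 M in CAST/EiJ and 31.9 to 43.4 M in NZO/HlLtJ. The series asks how strain and diet act together on gene expression. Strain set the libraries apart far more than diet. The first principal component held 57.7% of the variance and parted CAST/EiJ from the other strains, and the second held 22.4% and parted NZO/HlLtJ from C57BL/6J. On the third component, with 1.61%, C57BL/6J 10% fat replicate 4 scored 43.85, while the other libraries of the strain lay between -23.1 and 7.35. That library also had the lowest total, 21.9 M. On the fourth component, with 1.32%, NZO/HlLtJ 10% fat replicate 4 scored 27.4 and 44% fat replicate 3 scored 32, while the other 6 libraries of the strain lay between -21.7 and 0.793.

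**Figure D1:**
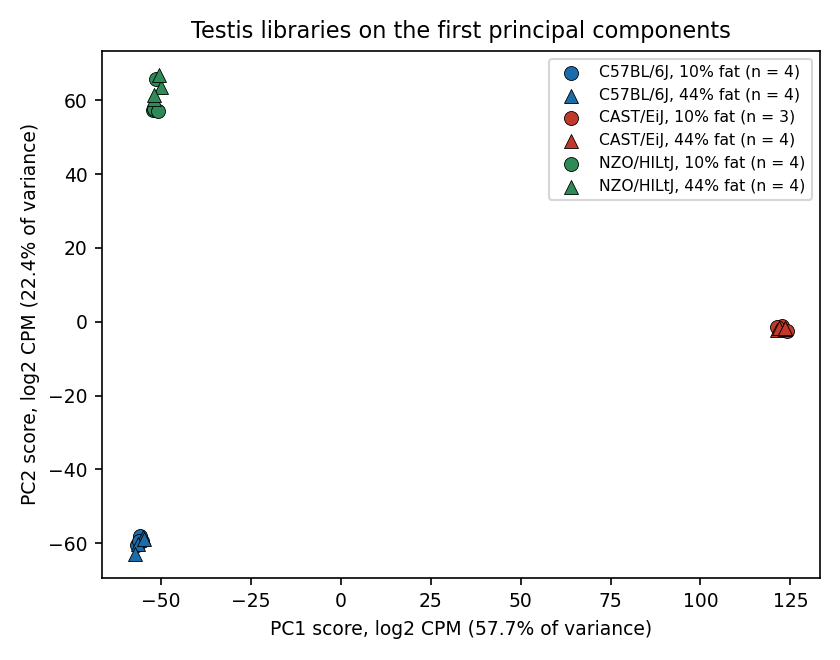
Scores of the 23 testis libraries on the first and second principal components of log2 CPM; color gives the strain and shape the diet. Libraries group by strain, with 57.7% of the variance on the first axis and 22.4% on the second, and the diets overlap.

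The comparison of NZO/HlLtJ with C57BL/6J asked which genes differ in the testis of the diabetes-prone strain. Markers of Leydig cells, which make testosterone, were higher in NZO/HlLtJ: Hsd3b1, of the steroid-forming 3-beta-hydroxysteroid dehydrogenases, stood at 317 ± 29.1 against 59.2 ± 6.75 CPM (n = 8 each), and Hsd17b3, which forms testosterone, at 58.5 ± 6.98 against 19.1 ± 1.13 CPM. Markers of undifferentiated spermatogonia were higher too, with the stem cell receptor Ret at 5.57 ± 0.544 against 1.42 ± 0.346 CPM and Lin28a at 8.61 ± 0.612 against 3.65 ± 0.32 CPM. Spermatid transcripts were lower by a smaller margin, with the sperm glycolysis enzyme Gapdhs at 1270 ± 115 against 1660 ± 78.4 CPM. In all, 13520 of 22873 genes (59.1%) passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 6959 higher and 6561 lower in NZO/HlLtJ, and 150 were at least 8-fold higher and 320 at least 8-fold lower.

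Of the 18 Leydig cell markers, 13 rose and 3 fell (median log2 fold change 0.72, camera adjusted p = 0.00051, but adjusted p = 0.339 with an estimated correlation). Among those that fell was Hsd3b6, an isoform related to Hsd3b1, at 4.96 ± 1.5 against 83.4 ± 18.2 CPM (n = 8 each). Reads can be shared between these genes, and their sum was 322 ± 28.8 CPM in NZO/HlLtJ against 143 ± 14.5 CPM in C57BL/6J. Undifferentiated spermatogonia markers rose in 8 and fell in 2 of 13 (median 0.70, adjusted p = 0.0094, but adjusted p = 0.309 with an estimated correlation), among them the transcription factor gene Sall4 at 8.8 ± 0.91 against 3.74 ± 0.577 CPM. Sertoli cell markers rose in 16 and fell in 1 of 22 (median 0.33, adjusted p = 0.00139, but adjusted p = 0.403 with an estimated correlation). The follicle-stimulating hormone receptor gene Fshr stood at 4.74 ± 0.708 against 1.69 ± 0.220 CPM and the inhibin gene Inha at 63.8 ± 7.65 against 38.6 ± 2.31 CPM, while Cst9 was lower, at 9.38 ± 0.670 against 69.2 ± 5.76 CPM. Genes of the blood-testis barrier and junctions rose in 11 and fell in 1 of 17 (median 0.22, adjusted p = 0.00106, but adjusted p = 0.293 with an estimated correlation). They include the laminin gene Lama1 with a log2 fold change of 1.36 (SE 0.05), the connexin gene Gja1 with 0.79 (SE 0.04) and F11r with 0.99 (SE 0.06).

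Insulin and IGF signalling genes rose in 15 and fell in 0 of 22 (median 0.38, adjusted p = 0.000251), the 1 list of this comparison that was called at both settings, with adjusted p = 0.0491 with an estimated correlation. The kinase gene Mtor stood at 567 ± 12.8 against 367 ± 6.26 CPM (n = 8 each), the receptor gene Igf1r at 61.7 ± 4.78 against 38.0 ± 3.31 CPM, and Foxo1, also a spermatogonia marker, at 21.2 ± 1.41 against 12.7 ± 1.16 CPM. Cholesterol synthesis genes rose in 17 and fell in 4 of 24 (median 0.47, adjusted p = 0.00106, but adjusted p = 0.403 with an estimated correlation). Stard4, which carries cholesterol between membranes, had a log2 fold change of 1.16 (SE 0.07) and Hmgcs1, of the mevalonate pathway, 0.47 (SE 0.04). Fatty acid oxidation and PPARA targets rose in 17 and fell in 5 of 27 (median 0.32, adjusted p = 0.00775, but adjusted p = 0.403 with an estimated correlation), with the fatty acid carrier gene Fabp3 at 200 ± 28.8 against 79.8 ± 7.12 CPM.

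Lists of late germ cells went the other way. Round spermatid markers fell in 15 and rose in 0 of 18 (median -0.22, adjusted p = 0.000251, but adjusted p = 0.403 with an estimated correlation), among them Spaca7 at -0.57 (SE 0.04) and Txndc8 at -0.44 (SE 0.04). Elongating spermatid markers fell in 15 and rose in 0 of 18 (median -0.25, adjusted p = 0.000251, but adjusted p = 0.403 with an estimated correlation), with Cabs1 at -0.36 (SE 0.04). Sperm motility and flagellum genes fell in 21 and rose in 1 of 26 (median -0.21, adjusted p = 0.000168, but adjusted p = 0.309 with an estimated correlation), including the sperm ion exchanger gene Slc9c1 at -0.50 (SE 0.05) and the axoneme gene Spag16 at -0.32 (SE 0.03). Genes of the piRNA pathway and transposon silencing fell in 11 and rose in 1 of 19 (median -0.11, adjusted p = 0.0392, but adjusted p = 0.403 with an estimated correlation), with the helicase gene Tdrd9 at -0.31 (SE 0.03) and the DNA methylation cofactor gene Dnmt3l at -0.92 (SE 0.10). For these 11 lists the counts of members adjusted over the list alone were the same, except 14 risen Leydig markers, 2 risen piRNA genes and 2 fallen junction genes. Genes of immediate early response and handling stress, a list not called, rose in 7 and fell in 1 of 14 (median 0.48, adjusted p = 0.138).

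The largest gene differences between NZO/HlLtJ and C57BL/6J approached presence or absence. Hist2h2aa2, a histone gene on chromosome 3, stood at 74.4 ± 4.86 CPM in NZO/HlLtJ against 0.125 ± 0.0987 CPM (n = 8 each), a fitted fold of 598, but it is a near copy of Hist2h2aa1, and the sum of both was 118 ± 7.16 against 140 ± 14.4 CPM. The globin gene Hba-a1 was at 6.67 ± 2.82 against 0.0292 ± 0.0827 CPM, and with its copy Hba-a2 at 17.3 ± 5.75 against 22.5 ± 6.99 CPM. Higher in NZO/HlLtJ by more than 50-fold were also the extracellular matrix gene Tnn at 16.1 ± 0.542 against 0.146 ± 0.0738 CPM, the myelin gene Mog, the peroxidase gene Lpo, the kinase gene Styk1 at 20.1 ± 1.79 against 0.279 ± 0.139 CPM, the multicopy X-linked gene Spin2f and the cadherin gene Dchs2. Itpr3os had 1 count over all NZO/HlLtJ libraries, a ratio to C57BL/6J of 0.00012 (95% interval 3.04e-06 to 0.00067), and the receptor-like gene Vmn2r7 a ratio of 0.000159 (4.01e-06 to 0.000884). Pnp2 was at 0 in NZO/HlLtJ and 8.26 ± 0.947 CPM in C57BL/6J, at least 844-fold lower, and its sum with the neighbouring copy Pnp was 5.51 ± 1.29 against 14.1 ± 1.31 CPM. Galntl6 was 263-fold lower at 0.350 ± 0.125 against 92.5 ± 6.41 CPM, Adam26a was 177-fold lower, and Agt, which encodes angiotensinogen, was 45.5-fold lower at 3.99 ± 1.19 against 181 ± 13.4 CPM. The ion channel gene Trpv1 and the macrophage gene Cd5l were 65.8-fold and 59.0-fold lower. The build named by the submitters is the C57BL/6J genome and any handling of strain variants is not given in the sources used here, so variants can lower counts in NZO/HlLtJ and CAST/EiJ. With a 2-fold limit 2468 genes passed, with the 10% fat groups alone 8826 and with the 44% fat groups alone 11526.

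The comparison of CAST/EiJ with C57BL/6J asked which genes differ in the wild-derived strain. Genes of the interferon response were lower in CAST/EiJ: 19 of 25 fell and 3 rose (median log2 fold change -0.87), with the antiviral gene Oasl2 at 0.687 ± 0.189 (n = 7) against 5.46 ± 0.857 CPM (n = 8) and Stat2 at 3.77 ± 0.513 against 7.98 ± 0.723 CPM. Of 21 genes of antigen presentation and MHC, 14 fell and 1 rose (median -0.68), with H2-K1 at 15.5 ± 1.31 against 48.3 ± 3.40 CPM and the class II chaperone gene Cd74 at 1.85 ± 0.508 against 10.3 ± 2.86 CPM. Of 11 markers of peritubular myoid and smooth muscle cells, 9 fell and 0 rose (median -0.42), with the muscle actin gene Actg2 at 90.6 ± 4.45 against 213 ± 11.4 CPM and the myosin kinase gene Mylk at 49.0 ± 1.67 against 70.7 ± 2.60 CPM. The flagellar dynein gene Dnah8 was higher, at 6330 ± 180 against 2760 ± 87.1 CPM. As given above, variants against the C57BL/6J build can lower counts in CAST/EiJ, and their part in these lower genes was not tested. In all, 15279 genes (66.8%) passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 7485 higher and 7794 lower in CAST/EiJ.

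Relative to all other genes, none of the 34 lists was called in this comparison by camera. The adjusted p was 0.0615 for the interferon response, 0.0615 for antigen presentation and MHC and 0.0725 for the myoid markers, and adjusted p = 0.913 with an estimated correlation for each of these. By fry, which asks whether the genes of a list move on balance one way, 17 lists were called, these among them at 3.84e-10, 1.71e-06 and 2.94e-10. The counts of fallen members were the same adjusted over the list alone. Other lists differed too in mean level, the log2 CPM of a list minus its mean over all libraries. On 10% and 44% fat, red blood cell genes were at -0.37 and -0.92 in CAST/EiJ against -0.04 and 0.11 in C57BL/6J. Epididymis and rete testis genes were at -0.44 ± 0.14 and -0.24 ± 1.08 against 0.79 ± 0.6 and 0.42 ± 0.17. The widest spreads were in the groups that each hold a library with epididymal transcripts, CAST/EiJ on 44% fat and C57BL/6J on 10% fat. Adipose markers were higher in CAST/EiJ, at 1.23 and 0.26 against -0.02 and 0.16. Without 1 library, CAST/EiJ 10% fat replicate 1, camera called 3 lists, and without any 1 of CAST/EiJ 44% fat replicate 2, C57BL/6J 44% fat replicate 2, C57BL/6J 10% fat replicate 3 and C57BL/6J 10% fat replicate 4, 2 lists.

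At least 8-fold higher in CAST/EiJ were 377 genes, and at least 8-fold lower 1043. The count table holds only genes above 0 in at least 12 libraries. A gene above 0 in CAST/EiJ alone, or in C57BL/6J alone, is thus missing, while one at 0 in CAST/EiJ alone can be present. With this filter and variants against the C57BL/6J build, the balance of higher and lower genes is uncertain. Among the largest increases were the cytochrome P450 gene Cyp2c70 at 10.1 ± 0.706 (n = 7) against 0.0188 ± 0.0323 CPM (n = 8), the insulin receptor-related gene Insrr at 21.4 ± 2.41 against 0.158 ± 0.118 CPM, the glucagon receptor gene Gcgr at 5.24 ± 0.608 against 0.0466 ± 0.0403 CPM and the lectin gene Reg3g at 8.19 ± 0.431 against 0.0821 ± 0.0572 CPM. Skint10, Zfp663, the homeobox gene Lmx1a and the hydroxysteroid dehydrogenase gene Akr1c21 were also more than 100-fold higher. Igfbp2, an IGF-binding protein gene, stood at 24.3 ± 3.16 against 4.97 ± 0.619 CPM and the cytokine signal inhibitor gene Socs2 at 12.2 ± 0.918 against 4.46 ± 0.467 CPM. The iron-binding protein gene Lcn2 was lower, at 14.1 ± 2.94 against 136 ± 15.4 CPM. Lower by more than 100-fold were the X-linked gene Samt1, Adam26a at 0.171 ± 0.138 against 74.8 ± 9.45 CPM, Pdzph1, Galntl6 at 0.353 ± 0.0985 against 92.5 ± 6.41 CPM, Smok3b, Klrb1 and the desmosome gene Dsg1a at 0.545 ± 0.203 against 65.2 ± 6.83 CPM. Members of the Samt, Adam26, Smok3, Klrb1 and Dsg1 families have close copies, so the assignment of reads to these genes is uncertain.

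The mitochondrial cytochrome oxidase gene mt-Co2 was counted at 2.26 ± 0.836 CPM in CAST/EiJ (n = 7) against 862 ± 53.0 CPM in C57BL/6J (n = 8) and 855 ± 57.6 CPM in NZO/HlLtJ (n = 8). Gm13341, a nuclear pseudogene on chromosome 2 whose transcript matches mt-Co2 at 656 of 672 aligned bases, went the other way, at 669 ± 94.9 CPM in CAST/EiJ against 0.0823 ± 0.0504 and 0.0950 ± 0.0484 CPM. It was named after its values were seen. The sum of mt-Co2 and Gm13341 was 671 ± 95.3 CPM in CAST/EiJ, 862 ± 53.0 in C57BL/6J and 855 ± 57.6 in NZO/HlLtJ. Among the other mitochondrial transcripts, mt-Nd2 was at 1560 ± 102 CPM in CAST/EiJ against 708 ± 31.6 CPM in C57BL/6J. With a 2-fold limit 5083 genes differed between CAST/EiJ and C57BL/6J, of which 1943 were higher and 3140 lower in CAST/EiJ. The limits of filter and build given above hold for this balance too.

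**Figure D2:**
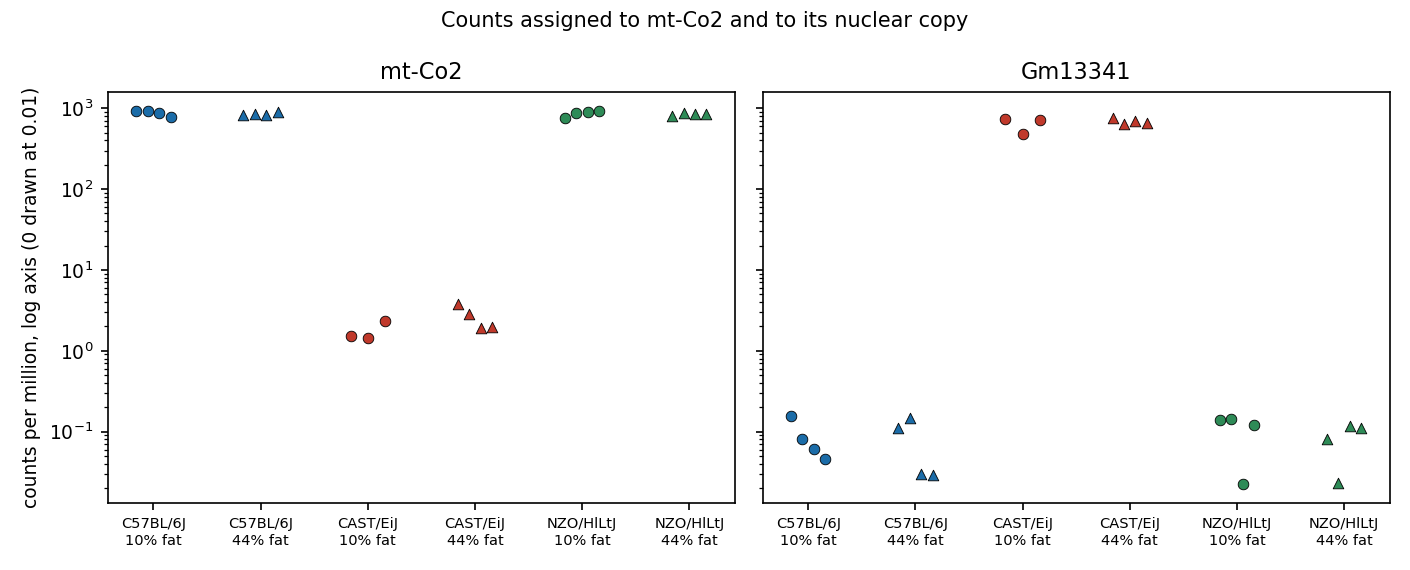
CPM (log axis) assigned to mt-Co2 on the left and to its nuclear copy Gm13341 on the right, 1 point per library, by strain and diet. In CAST/EiJ the counts sit on Gm13341, with a mean of 669 CPM against 2.26 CPM for mt-Co2, and in the other strains on mt-Co2.

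NZO/HlLtJ against CAST/EiJ completed the pairs of strains. Interferon response genes were higher in NZO/HlLtJ, with 21 of 25 risen and 2 fallen (median log2 fold change 1.26, camera adjusted p = 0.00291, but adjusted p = 0.275 with an estimated correlation). Oasl2 stood at 6.02 ± 0.918 (n = 8) against 0.687 ± 0.189 CPM (n = 7). Variants can lower counts in both strains, as given above. All 11 myoid and smooth muscle markers rose (median 0.73, adjusted p = 0.000716, but adjusted p = 0.275 with an estimated correlation), with Actg2 at 173 ± 9.19 against 90.6 ± 4.45 CPM and Mylk at 83.3 ± 2.68 against 49.0 ± 1.67 CPM. Leydig markers rose in 12 and fell in 4 of 18 (median 0.83, adjusted p = 0.0353, but adjusted p = 0.79 with an estimated correlation), with Fabp3 at 200 ± 28.8 against 40.6 ± 2.60 CPM and Hsd3b1 at 317 ± 29.1 against 67.6 ± 6.89 CPM. Hsd3b6 stood at 4.96 ± 1.5 against 32 ± 5.07 CPM, and the sum of Hsd3b1 and Hsd3b6 at 322 ± 28.8 against 99.6 ± 9 CPM. In all, 16482 genes (72.1%) passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 9056 higher and 7426 lower in NZO/HlLtJ, with 928 at least 8-fold higher and 449 at least 8-fold lower.

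Lower in NZO/HlLtJ than in CAST/EiJ were late germ cell and adipose lists. Elongating spermatid markers fell in 16 and rose in 0 of 18 (median -0.30, adjusted p = 0.000618, but adjusted p = 0.79 with an estimated correlation), with the transition protein gene Tnp1 at 1370 ± 108 (n = 8) against 1920 ± 79.5 CPM (n = 7) and Hmgb4 at 277 ± 16 against 418 ± 20.3 CPM. Sperm motility and flagellum genes fell in 22 and rose in 1 of 26 (median -0.32, adjusted p = 1.85e-05, but adjusted p = 0.275 with an estimated correlation), with the dynein genes Dnah8 at 2780 ± 102 against 6330 ± 180 CPM and Dnah17 at 900 ± 26.3 against 1320 ± 56.7 CPM. Genes of the piRNA pathway fell in 11 and rose in 3 of 19 (median -0.24, adjusted p = 0.0407, but adjusted p = 0.607 with an estimated correlation), with Piwil1 at 368 ± 19.5 against 540 ± 19.3 CPM and Tdrd1 at 209 ± 6.95 against 279 ± 5.68 CPM. Adipose tissue markers fell in 7 and rose in 0 of 11 (median -0.92, adjusted p = 0.0409, but adjusted p = 0.79 with an estimated correlation). These included Thrsp at 0.376 ± 0.126 against 6.19 ± 1.12 CPM, the lipid droplet gene Plin1 at 2.08 ± 0.365 against 5.93 ± 1.22 CPM and the adipocyte protease gene Cfd at 0.0847 ± 0.0917 against 1.84 ± 1.73 CPM. The counts for these 7 lists were the same adjusted over the list alone. Beside them, some lists not called were higher in NZO/HlLtJ. Interstitial fibroblasts rose in 9 and fell in 2 of 12 (median 0.72, camera adjusted p = 0.129). Immediate early response and handling stress rose in 8 and fell in 2 of 14 (median 0.56, camera adjusted p = 0.472). Mean levels of inflammatory genes were 0.23 and 0.31 on 10% and 44% fat against -0.29 and -0.25 in CAST/EiJ. Those of red blood cell genes were 0.7 and 0.43 against -0.37 and -0.92. The sum of Hba-a1 and Hba-a2 was 17.3 ± 5.75 against 17.6 ± 6.48 CPM. Antioxidant genes were lower in NZO/HlLtJ, at -0.02 and -0.06 against 0.15 and 0.15.

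Among the largest single differences, Samt1, Pdzph1, Klrb1, Smok3b and the X-linked multicopy gene Spin2g were more than 100-fold higher in NZO/HlLtJ than in CAST/EiJ, with the doubt about reads of close copies given above. Hist2h2aa2 and mt-Co2 were too, but the sum of Hist2h2aa1 and Hist2h2aa2 was lower, at 118 ± 7.16 (n = 8) against 198 ± 11.9 CPM (n = 7), and that of mt-Co2 and Gm13341 was 855 ± 57.6 against 671 ± 95.3 CPM. Mog had 1 to 3 counts over the CAST/EiJ libraries and a count ratio of 577 (95% interval 197 to 2800). Reg3g, Cyp2c70, Zfp663, Insrr and the melanocortin receptor gene Mc5r were more than 100-fold higher in CAST/EiJ, as was the vomeronasal receptor gene Vmn2r6. Itpr3os and Vmn2r7 had 1 count over the NZO/HlLtJ libraries, ratios of 0.00013 (3.29e-06 to 0.000724) and 0.000556 (1.41e-05 to 0.0031). With a 2-fold limit 5189 genes differed. The limits of filter and build hold here as well.

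**Figure D3:**
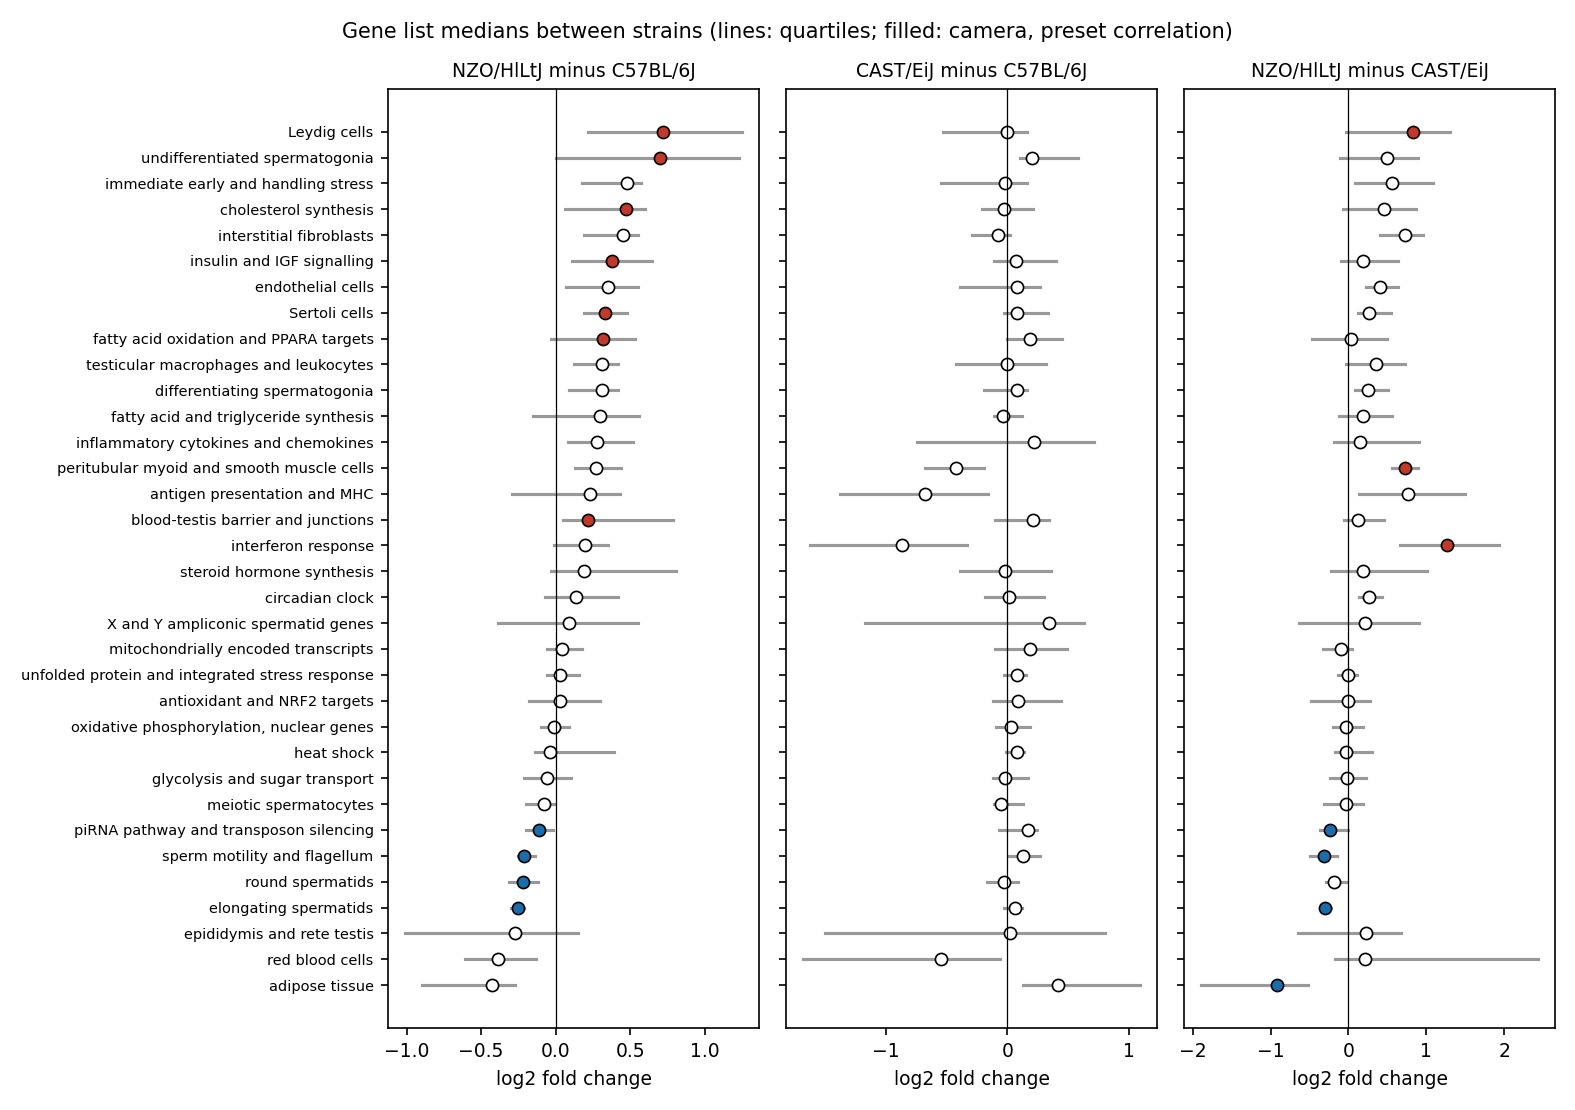
Median log2 fold change of each of the 34 gene lists between pairs of strains, with lines from the first to the third quartile of the list's genes; filled points passed camera at the preset correlation. Leydig markers lie highest in NZO/HlLtJ against C57BL/6J at 0.72, and the interferon response highest in NZO/HlLtJ against CAST/EiJ at 1.26.

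For diet in C57BL/6J, 2 gene copies of the Fam205a family and no other gene passed the threshold. Fam205a2 (GRCm38 chromosome 4, 42522580 to 42528175) and Fam205a3 (chromosome 4, 42318334 to 42323929) each stood at 16.7 ± 3.11 CPM on 44% fat against 9.44 ± 1.17 CPM on 10% fat (n = 4 each), a log2 fold change of 0.82 (SE 0.14) with adjusted p = 0.0283. All 4 libraries on 44% fat lay above the mean of those on 10% fat. The transcripts are 100% identical over 3927 bases, so both values rest on the same reads and count as 1 signal. The whole Fam205a2 transcript also lies in that of Fam205a4, at 100% identity over 3927 bases, and Fam205a4 stood at 96 ± 16.3 CPM on 44% fat against 104 ± 5.99 CPM on 10% fat. The sum of Fam205a2, Fam205a3 and Fam205a4 was 129 ± 10.4 against 123 ± 6.74 CPM (n = 4 each), a difference that an exact two-sided permutation test chosen after the values were seen did not set apart (p = 0.4, smallest possible 0.0286). A change of the Fam205a copies together was thus not shown. At an unadjusted p under 0.05 there were 670 genes, where 1144 would be expected by chance. Genes with the next smallest p, all with adjusted p = 1, were the mucin gene Muc5b, the thyroid hormone deiodinase gene Dio1 at 0.637 ± 0.239 against 1.28 ± 0.470 CPM, Aggf1 at 32.2 ± 1.05 against 36.2 ± 1.75 CPM, Clec3b at 1.43 ± 0.398 against 2.31 ± 0.395 CPM and Lrrc4b at 1.33 ± 0.401 against 0.748 ± 0.0783 CPM. The Muc5b value of -2.61 (SE 0.64) rested on 119 CPM in 10% fat replicate 2, without which it was 0.15.

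As sets, cholesterol synthesis genes (median log2 fold change -0.09, camera adjusted p = 4.65e-05), nuclear genes of oxidative phosphorylation (-0.06, 6.2e-05), Leydig markers (-0.09, 0.00662), steroid hormone synthesis (-0.09, 0.0269) and antioxidant genes (-0.04, 0.0269) were lower on 44% fat in C57BL/6J. All 5 calls were lost with adjusted p = 0.74 with an estimated correlation. None of their members passed over all genes tested, and 0 did when adjusted over the list alone. Cyp17a1, an enzyme gene of androgen synthesis, stood at 250 ± 44.7 against 321 ± 28.1 CPM, a log2 fold change of -0.36 (SE 0.13) that did not pass, and values for the cholesterol carrier gene Star (-0.09), Insl3 (-0.04) and Nnt (-0.01) did not either. The Fam205a2 and Fam205a3 calls ended with limma voom, in a fit of the 2 groups alone, and when any 1 of 6 libraries was left out (10% fat replicates 1, 3 and 4, and 44% fat replicates 1, 2 and 4). Camera called 2 lists without 44% fat replicate 2 or 3, 3 without 10% fat replicate 1 or 2, 8 without 44% fat replicate 1 or 10% fat replicate 4, and 9 without 44% fat replicate 4.

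Diet in CAST/EiJ changed 0 genes at the threshold by edgeR, with 941 genes at an unadjusted p under 0.05 where 1144 would be expected by chance. DESeq2 called 3 genes (Gm3095, Mark1-ps3 and RP24-344N22.3), and limma voom and limma on the deposited log2 values each called 1, the ion channel gene Trpc2. Smallest p values among named genes belonged to the synuclein gene Sncb at 3.63 ± 0.382 CPM on 44% fat (n = 4) against 2.18 ± 0.449 CPM on 10% fat (n = 3), with adjusted p = 0.589, and to Ngfr at 3.37 ± 0.120 against 2.36 ± 0.233 CPM, the collagen gene Col2a1 at 0.974 ± 0.195 against 1.51 ± 0.176 CPM and Dscaml1 at 0.609 ± 0.121 against 1.00 ± 0.189 CPM, each with adjusted p = 0.636. Wfdc16 had a fitted log2 value of 4.59 (SE 1.16) that rested on 8.20 CPM in 44% fat replicate 2, a library that also held 99.0 CPM of the epididymal gene Crisp1 against at most 0.188 CPM in the other 6. Cyp17a1 stood at 154 ± 21.8 against 183 ± 42.7 CPM, and the log2 values of Star (-0.36), Insl3 (-0.17) and Nnt (0.00) did not pass either.

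Cholesterol synthesis genes were lower on 44% fat in CAST/EiJ as a set (median -0.15, camera adjusted p = 2.09e-06), as were adipose markers (-0.74, 2.09e-06), red blood cell genes (-0.48, 0.00237), spermatocyte markers (-0.05, 0.00842) and interferon response genes (-0.15, 0.0127). All 5 calls were lost with adjusted p = 0.432 with an estimated correlation. Among cholesterol genes 0 fell over all genes tested and 2 of 24 adjusted over the list alone. Without 44% fat replicate 3, edgeR called 3 genes for diet in CAST/EiJ, Gm3095, Mark1-ps3 and Trpc2, and without 44% fat replicate 1 camera called 9 lists.

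For diet in NZO/HlLtJ, Slc38a2, which encodes an amino acid transporter (chromosome 15, 96687394 to 96699698), was higher at 68.2 ± 10.1 CPM on 44% fat against 47.6 ± 4.35 CPM on 10% fat (n = 4 each), with a log2 fold change of 0.52 (SE 0.09) and adjusted p = 0.0363. All 4 libraries on 44% fat lay above the mean of those on 10% fat. In C57BL/6J the gene stood at 39.5 ± 2.05 against 39.6 ± 4.56 CPM (n = 4 each), and in CAST/EiJ at 45 ± 3.13 (n = 4) against 47.1 ± 3.61 CPM (n = 3). Next by p, and not past the threshold, were the ganglioside enzyme gene St8sia1 at 9.12 ± 1.63 against 6.31 ± 0.581 CPM, Pakap at 9.63 ± 1.35 against 5.61 ± 1.26 CPM and Eno1b at 3.11 ± 0.302 against 4.34 ± 0.165 CPM, each with adjusted p = 0.224, and the phosphatase gene Ptpn13 with adjusted p = 0.267. Eno1b is a close copy of Eno1, which stood at 335 ± 20.2 CPM in NZO/HlLtJ (n = 8), so the assignment of its reads is uncertain. At an unadjusted p under 0.05 there were 1555 genes, where 1144 would be expected by chance. Other splits of the same libraries gave 554 to 2656 such genes, so the excess alone does not show a diet effect. DESeq2 called 7 genes, among them St8sia1, Pakap, Eno1b, Ptpn13, Slc38a2 and Gm20775.

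**Figure D4:**
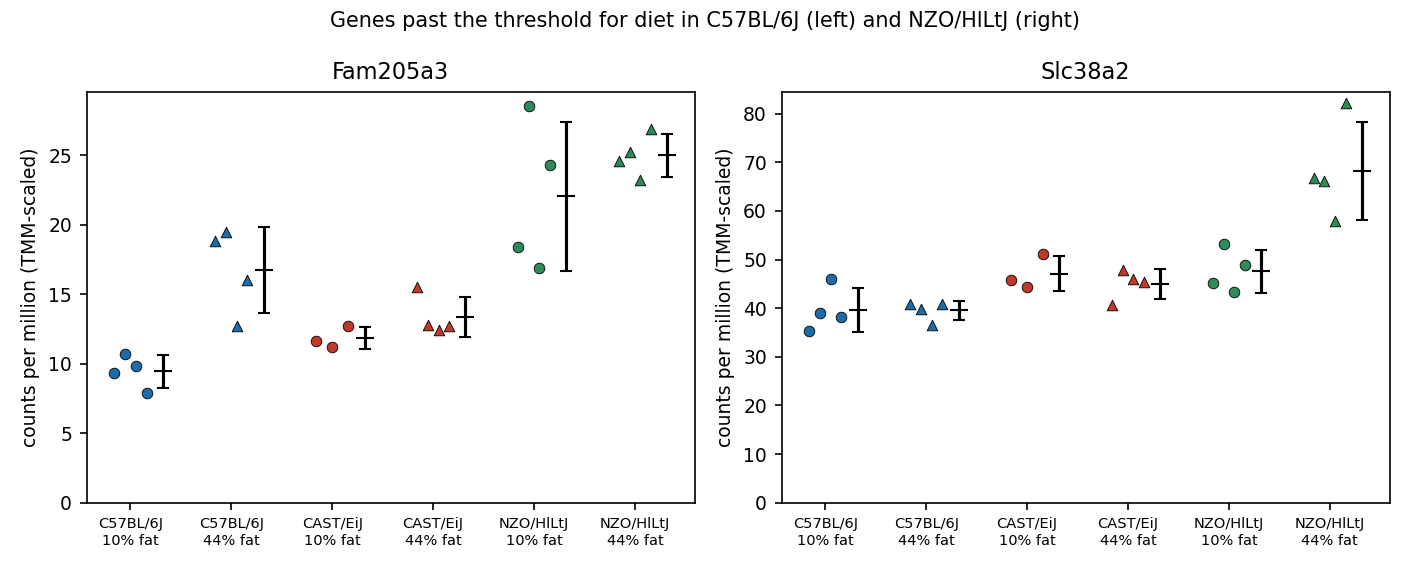
CPM of Fam205a3 (left) and Slc38a2 (right) per library, by strain and diet; bars give the mean and SD of each group. On 44% fat, Fam205a3 stood at 16.7 against 9.44 CPM in C57BL/6J, where its sum with the copies Fam205a2 and Fam205a4 was 129 against 123 CPM, and Slc38a2 at 68.2 against 47.6 CPM in NZO/HlLtJ.

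Nuclear genes of oxidative phosphorylation were lower on 44% fat in NZO/HlLtJ (median -0.10, camera adjusted p = 3.84e-09, but adjusted p = 0.709 with an estimated correlation). Round spermatid (-0.05, 0.00569), elongating spermatid (-0.07, 0.0248), cholesterol synthesis (-0.06, 0.0378) and sperm motility genes (-0.01, 0.0378) were lower too, each with adjusted p = 0.739 with an estimated correlation. Antigen presentation and MHC genes (0.15, 0.00305) and Sertoli markers (0.06, 0.0248) were higher, also with adjusted p = 0.739 with an estimated correlation. Insulin and IGF signalling genes were higher (0.10, 0.0235, but adjusted p = 0.561 with an estimated correlation), as were junction genes (0.06, 0.0235, but adjusted p = 0.709 with an estimated correlation), of which 1 rose adjusted over the list alone. Camera called 9 lists here, but 2 without 44% fat replicate 3 and 3 without 10% fat replicate 3. The steroid genes Star (-0.32) and Cyp17a1 (-0.20), and Insl3 (0.17) and Nnt (0.01), did not pass, and Star turned to 0.03 with the run of ID numbers as a covariate. The Slc38a2 call ended with the run of ID numbers as a covariate, in a fit of the 2 groups alone, and without any 1 of 10% fat replicates 1 and 3 and 44% fat replicates 1, 2 and 4. Without 10% fat replicate 4, 5 genes were called (Slc38a2, Gramd1a, Ildr2, the acute phase gene Serpina3n and the complement gene C4b), and without 10% fat replicate 2, 2 genes.

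Averaged over strains, diet changed 0 genes at the threshold by edgeR, with 896 at an unadjusted p under 0.05 where 1144 would be expected by chance. DESeq2 called 4 (Fam205a2, Fam205a3, Gm3095 and Gm44280) and both limma fits 0. Genes of cholesterol synthesis were lower on 44% fat in the averaged comparison (median -0.10, camera adjusted p = 2.38e-12, but adjusted p = 0.409 with an estimated correlation), with 5 of 24 fallen adjusted over the list alone and 0 over all genes tested. Fdps, of the mevalonate pathway, was at 57.8 ± 1.89 against 64.7 ± 2.04 CPM in C57BL/6J (n = 4 each), 54.5 ± 1.16 (n = 4) against 58.8 ± 4.50 CPM (n = 3) in CAST/EiJ and 77.8 ± 1.11 against 85.4 ± 7.23 CPM in NZO/HlLtJ (n = 4 each), with adjusted p = 0.346. Nuclear genes of oxidative phosphorylation (-0.05, 1.24e-10), steroid hormone synthesis (-0.06, 0.000595), adipose markers (-0.23, 0.00236), red blood cell genes (-0.21, 0.00557) and spermatocyte markers (-0.02, 0.0359) were lower as sets, each with adjusted p = 0.432 with an estimated correlation. The adipose and red blood cell medians lay below 0 in CAST/EiJ (-0.74 and -0.48) and NZO/HlLtJ (-0.13 and -0.32) but above 0 in C57BL/6J (0.19 and 0.09), and passed in CAST/EiJ alone. Leydig markers were lower (-0.06, 0.0485, but adjusted p = 0.501 with an estimated correlation). Adjusted over the list alone, 3 genes fell and 1 rose in each of the steroid and Leydig lists. The log2 values of Cyp17a1 (-0.27, SE 0.08), Star (-0.26, SE 0.15), Insl3 (-0.01) and Nnt (0.00) did not pass over all genes, and Fam205a2 and Fam205a3 (0.39, SE 0.08) had adjusted p = 0.176. Oprd1 (0.47, SE 0.10) had adjusted p = 0.308 and the chemokine gene Ccl28 (-0.56, SE 0.13) 0.346. Without NZO/HlLtJ 10% fat replicate 2 or C57BL/6J 44% fat replicate 3 edgeR called 2 genes, and without C57BL/6J 10% fat replicate 4 or CAST/EiJ 44% fat replicate 3, 1 gene. Without NZO/HlLtJ 10% fat replicate 4 camera called 17 lists.

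**Figure D5:**
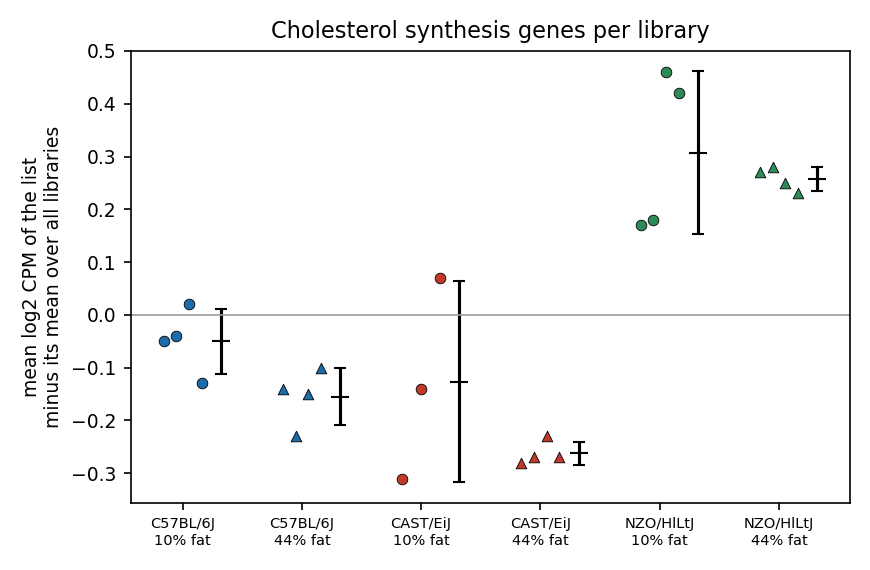
Mean log2 CPM of the cholesterol synthesis genes per library, minus its mean over all 23 libraries, by strain and diet; bars give the mean and SD of each group. The list was at -0.16 on 44% fat against -0.05 on 10% fat in C57BL/6J, and 0.26 and 0.31 in NZO/HlLtJ.

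The test of strain by diet asked whether diet acted differently in the strains, which is the question in the title of the series. The adaptor gene Pakap came nearest: it stood at 6.67 ± 0.631 CPM on 44% fat against 9.38 ± 0.860 CPM on 10% fat in C57BL/6J, and at 9.63 ± 1.35 against 5.61 ± 1.26 CPM in NZO/HlLtJ (n = 4 each). The difference of the diet effects was 1.27 on the log2 scale (SE 0.23, adjusted p = 0.107). Among the genes named between NZO/HlLtJ and C57BL/6J, Zc3h12b followed with 1.04 (SE 0.23, adjusted p = 0.47). For Slc38a2 the difference was 0.52 (SE 0.12, adjusted p = 0.814) between NZO/HlLtJ and C57BL/6J and 0.59 (SE 0.13, adjusted p = 0.337) between NZO/HlLtJ and CAST/EiJ, so its call in NZO/HlLtJ alone is not shown to be specific to that strain. An entry for Sgsm3 (chromosome 15, 81002628 to 81011736), which lies inside a longer gene of the same symbol, stood at 3.26 ± 1.09 against 7.46 ± 3.48 CPM in NZO/HlLtJ (n = 4 each) and at 13.5 ± 4.38 (n = 4) against 7.43 ± 1.92 CPM (n = 3) in CAST/EiJ, a difference of -2.06 (SE 0.39, adjusted p = 0.337). Crisp1 (12.67, SE 2.98) and Serpina16 (8.08, SE 2.00) had the smallest p values between CAST/EiJ and C57BL/6J, each with adjusted p = 0.809, and rested on single libraries of both strains. Other genes with the smallest p were Ifngr1 (0.43) and Tead1 (0.42) between NZO/HlLtJ and C57BL/6J, Col2a1 (-0.65), Dffa (-0.48) and Rfx7 (-0.30) between CAST/EiJ and C57BL/6J, and Eno1b (-0.58) and Hspbap1 (-0.44) between NZO/HlLtJ and CAST/EiJ, none past the threshold, and Nnt differed by at most 0.02.

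By edgeR 0 genes passed the test over all strains, with 1121 at an unadjusted p under 0.05 where 1144 would be expected by chance, and 0 passed in each pair, with 926 for NZO/HlLtJ against C57BL/6J, 919 for CAST/EiJ against C57BL/6J and 1704 for NZO/HlLtJ against CAST/EiJ. Other splits of the libraries gave up to 2071 for the last pair, so its 1704 genes alone do not show an interaction. DESeq2 called 7 genes over all strains, among them Pakap and Slc38a2, 2 for NZO/HlLtJ against C57BL/6J (Pakap and 4930408K08Rik) and 0 for the other pairs, and both limma fits called 0 throughout. Across 17256 genes the log2 effects of diet had a Pearson r of -0.11 between C57BL/6J and CAST/EiJ, 0.033 between C57BL/6J and NZO/HlLtJ and -0.03 between CAST/EiJ and NZO/HlLtJ (Spearman's rho -0.024, 0.042 and -0.164). These are correlations across genes, which are not independent replicates. Leaving out NZO/HlLtJ 10% fat replicate 4 gave 1 gene over all strains and 1 against CAST/EiJ. Leaving out CAST/EiJ 44% fat replicate 3 gave 2 for that pair, and leaving out any 1 of NZO/HlLtJ 10% fat replicates 1 and 2 and C57BL/6J 44% fat replicate 4 gave 1 for NZO/HlLtJ against C57BL/6J.

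Nnt, a mitochondrial transhydrogenase gene with a known deletion of exons in C57BL/6J, was used to check strain labels. A lower count was predicted in C57BL/6J. Its counts were 60.6 ± 2.65 CPM in C57BL/6J (n = 8), 95 ± 3.35 CPM in CAST/EiJ (n = 7) and 55.1 ± 1.69 CPM in NZO/HlLtJ (n = 8). C57BL/6J lay 0.23 below the other strains together on the log2 scale, which an exact two-sided permutation test did not set apart (p = 0.121). Against CAST/EiJ alone the difference was -0.65 (exact permutation p = 0.000155) and against NZO/HlLtJ alone 0.14 (exact permutation p = 0.000311). The predicted lower count was thus found against CAST/EiJ only, and the check did not bear out the strain labels as planned. Counts per gene sum all exons and do not show which exons were read, so the deletion itself was not examined.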

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

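The tests on epididymal transcripts, on the share of spermatids, on the NZO/HlLtJ libraries apart on the fourth principal component and on mt-Co2 were chosen only after the result was seen. The splits of libraries and the test of library scaling were planned.

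CAST/EiJ 44% fat replicate 2 stood apart through transcripts of the epididymis, with 99.0 CPM of the sperm-binding protein gene Crisp1 against 0 to 0.0796 CPM in the other 3 libraries of its group, 11.1 of Serpina16 and 8.20 of Wfdc16 and, chosen after their values were seen, 41 of Cuzd1 (at most 3.79 in other CAST/EiJ libraries), 14.7 of Ces5a and 10.4 of Prom2 (at most 0.162). C57BL/6J 10% fat replicate 2 raised the same genes, with 13.0 CPM of Crisp1, 2.57 of Serpina16, 9.35 of Cuzd1, 5.03 of Ces5a and 2.14 of Prom2, and held 119 CPM of Muc5b against 4.82 to 5.23 in its group. A response shared by the 44% fat group is argued against, since 0 of the other 3 CAST/EiJ libraries on that diet held more Crisp1 than the highest on 10% fat and the C57BL/6J library came from the 10% fat diet. Epididymal or duct cells in the sampled tissue may be the source, and the joint rise of these genes in libraries of both strains would go with it, but only 4 of the 8 other tested members of the list written for that tissue (Rnase10, Pax8, Krt8 and Krt18) peaked in the CAST/EiJ library among libraries of the strain. That source and a difference of the animals cannot be told apart, because Rnase10 at 0.129 and Teddm1a at 0.0776 CPM stayed near 0, Cst8 at 60.3 CPM lay within the 52.3 to 64.0 of the other CAST/EiJ libraries, and Krt8 and Aqp1 are also expressed there.

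The shift of 11 gene lists between NZO/HlLtJ and C57BL/6J went up in Leydig, Sertoli and spermatogonia markers and down in spermatid genes, and the genes of immediate early response and handling stress, a list not called, went up beside it (median 0.48, adjusted p = 0.138). The 2 NZO/HlLtJ libraries apart on the fourth component are argued against, since 10 of the 11 lists were called without them, while the count of 0 lists that changed the sign of the median under RLE size factors decides nothing about library scaling, as that setting moves all genes alike by less than any of these medians. A lower share of spermatids in NZO/HlLtJ may underlie the pattern, and the means of 6 lists of other cell types, which it should raise alike, were spread no wider than those of permuted lists (permutation p = 0.791 over genes). It should also leave earlier germ cells no lower, yet spermatocyte markers fell in 11 and rose in 3 of 22 (median -0.08, adjusted p = 0.0801), while myoid (median 0.27), endothelial (0.35), fibroblast (0.45) and leukocyte markers (0.31, with a mean of 0.06) were higher without being called. Lists as wide as these decide neither way, so a change in cell shares and a change in expression per cell cannot be told apart here, and handling and strain itself stay open as untested causes.

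For mt-Co2, far lower in CAST/EiJ than in C57BL/6J, reads assigned to the nuclear copy Gm13341 are a candidate cause, since the log2 difference of the sum of both was -0.37 where mt-Co2 alone gave -8.59. Fewer mitochondrial transcripts in CAST/EiJ are argued against, as the other mitochondrially encoded transcripts had a median log2 fold change of 0.23. Reads could move to the copy through a strain variant against the reference, which was not tested.

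Other splits of the same libraries show where chance can be excluded. For strain counts 1 of 40 splits, the real one, gave as many genes: 13520 against at most 9317 otherwise for NZO/HlLtJ and C57BL/6J, 15279 against 10802 for CAST/EiJ and C57BL/6J, and 16482 against 12346 for NZO/HlLtJ and CAST/EiJ. For diet in C57BL/6J 2 of 35 splits gave at least 2 genes, so chance is not excluded for the Fam205a copies. The other one called 89 genes and set 10% fat replicates 1 and 2 and 44% fat replicates 1 and 4 against the rest. The former include both libraries of ID run 1, but runs 2 and 3 had libraries on both sides. On the fourth principal component the former scored 6.63 to 8.45 and the rest -11.3 to 1.7. This points to a structure of the samples apart from diet. Fam205a2 and Fam205a3 count as 1 signal, so splits of C57BL/6J that called 1 gene match it too, and further splits did so. For diet in NZO/HlLtJ 12 of 35 splits gave at least 1 gene, and chance is not excluded. The highest, with 165 genes, is the diet split with 10% fat replicate 4 and 44% fat replicate 1 exchanged. It puts the libraries apart on the fourth principal component, 10% fat replicate 4 (27.4) and 44% fat replicate 3 (32), on the same side, while diet parts them. Its count points to a structure of the samples that overlaps with diet only in part. Without 10% fat replicate 4, 5 genes were called for diet. With the run as a covariate the real counts were 2 in C57BL/6J and 0 in NZO/HlLtJ. The real count was 0 in 6 comparisons, where 35 of 35 splits must give as many, so that these splits test nothing about chance: diet in CAST/EiJ (highest other 5), averaged over strains (2), all interactions (2), NZO/HlLtJ against C57BL/6J (3), CAST/EiJ against C57BL/6J (2) and NZO/HlLtJ against CAST/EiJ (2).

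For the count of lists called by camera, chance is not excluded in any comparison with a list called, and CAST/EiJ against C57BL/6J, with 0 lists called, gives no test. As many as the real count came in 11 of 35 splits for diet in C57BL/6J (real 5, highest other 11), 20 in CAST/EiJ (5 and 11), 17 in NZO/HlLtJ (9 and 23) and 14 averaged over strains (7 and 15). In the interactions they came in 9 of 35 for NZO/HlLtJ and C57BL/6J (10 and 21), 14 for CAST/EiJ and C57BL/6J (5 and 10) and 22 for NZO/HlLtJ and CAST/EiJ (5 and 20). Between strains they came in 11 of 40 for NZO/HlLtJ and C57BL/6J (11 and 21), 40 for CAST/EiJ and C57BL/6J (0 and 8) and 15 for NZO/HlLtJ and CAST/EiJ (7 and 15).

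The diet effect on some lists differed between strains by camera. Between NZO/HlLtJ and C57BL/6J, the effect in NZO/HlLtJ was higher for Sertoli cells (adjusted p = 0.0204), Leydig cells (0.0423), leukocytes (0.0204), interstitial fibroblasts (0.0195), insulin and IGF signalling (0.0423), antigen presentation and MHC (0.0423) and junctions (0.0204), and lower for round spermatids (0.00128), elongating spermatids (0.00373) and sperm motility (0.00388). All 10 were lost, with adjusted p = 0.706 with an estimated correlation, and 0.803 for antigen presentation and MHC. Between CAST/EiJ and C57BL/6J, the effect in CAST/EiJ was higher for leukocytes (0.0313, a list that includes Cd52, which peaked in the library with epididymal transcripts) and oxidative phosphorylation (0.0423), and lower for adipose tissue (1.25e-05), red blood cells (0.0234) and the interferon response (0.0313). These were lost with adjusted p = 0.625 with an estimated correlation for the last 3, 0.844 for leukocytes and 0.857 for oxidative phosphorylation. Between NZO/HlLtJ and CAST/EiJ, the effect in NZO/HlLtJ was higher for fibroblasts (0.0124), the interferon response (0.0124) and antigen presentation and MHC (0.0024), and lower for round spermatids (0.00467) and oxidative phosphorylation (0.00145), with adjusted p = 0.868 with an estimated correlation for the interferon response, 0.897 for oxidative phosphorylation and 0.88 for the rest. Single libraries moved these counts: for NZO/HlLtJ and C57BL/6J to 4 lists without NZO/HlLtJ 10% fat replicate 2 and 2 without NZO/HlLtJ 44% fat replicate 3. For CAST/EiJ and C57BL/6J the count was 2 without C57BL/6J 44% fat replicate 1 or CAST/EiJ 44% fat replicate 1, 1 without C57BL/6J 44% fat replicate 2 and 3 without CAST/EiJ 44% fat replicate 2. For NZO/HlLtJ and CAST/EiJ it was 3 without NZO/HlLtJ 10% fat replicate 2 or CAST/EiJ 44% fat replicate 4, 1 without NZO/HlLtJ 44% fat replicate 2, and 10, 9 and 13 without NZO/HlLtJ 44% fat replicate 1, CAST/EiJ 44% fat replicate 2 and NZO/HlLtJ 10% fat replicate 4.

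Single libraries far from the others of their group or strain, as a gap test finds them in about 1 of 20 groups by chance, were found in 1 of 5 groups for totals, 5 of 170 for lists (8 expected) and 26 of 306 for genes (15 expected). CAST/EiJ 44% fat replicate 1 had a total of 78.7 M counts against 35.1 to 39.4 M. NZO/HlLtJ 10% fat replicate 4 lay apart in the level of insulin and IGF signalling (0.290 against 0.112 to 0.122), of junction genes (0.234 against 0.128 to 0.131) and in Insl3 (241 against 133 to 142 CPM). List levels apart were also -0.03 for undifferentiated spermatogonia in CAST/EiJ 44% fat replicate 3, -0.033 for spermatocytes in C57BL/6J 44% fat replicate 4 and -0.072 for the circadian clock in C57BL/6J 10% fat replicate 3.

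Within diet groups, lone values were 6.58 CPM of Muc5b in C57BL/6J 44% fat replicate 1, 6.73 of Dffa in C57BL/6J 10% fat replicate 3, 15.5 of Fam205a2 and of Fam205a3 in CAST/EiJ 44% fat replicate 1, 4.59 of Eno1b in NZO/HlLtJ 10% fat replicate 3 and 7.61 of Pakap in NZO/HlLtJ 44% fat replicate 2. Within strains, C57BL/6J held 0.581 CPM of Styk1 in 10% fat replicate 3, 5.01 of Sall4 and 569 of Cabs1 in 10% fat replicate 4, 23.1 of Lama1 in 44% fat replicate 1 and 1.70 of Thrsp in 44% fat replicate 2. CAST/EiJ held 0.12 CPM of Dsg1a and 461 of Hmgb4 in 10% fat replicate 1, 0.129 of Pdzph1 and 267 of Tdrd1 in 44% fat replicate 2, and 6.42 of Vmn2r7 and 12.3 of Per2 in 44% fat replicate 3. NZO/HlLtJ held 24.2 CPM of Foxo1 in 44% fat replicate 3 and 1620 of Tnp1 in 10% fat replicate 3.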

How the results depend on the processing

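Leaving out the 2 libraries with epididymal transcripts, or the 2 NZO/HlLtJ libraries apart on the fourth principal component, was chosen after seeing the data. The other alternatives were planned. No gene named in strain comparisons changed direction in a setting or without a library where it had a value. Stricter filters left some of these genes without one, and some no longer passed, most of them under the 2-fold limit. Counts without 1 library ran from 13027 to 13380 for NZO/HlLtJ against C57BL/6J, 14862 to 15099 for CAST/EiJ against C57BL/6J and 16105 to 16284 for NZO/HlLtJ against CAST/EiJ. With a 2-fold limit these counts were 2468, 5083 and 5189. For the first, the 10% fat groups alone gave 8826 and the 44% fat groups alone 11526, both from fewer samples. Under RLE size factors 47.1% of the genes that differed between NZO/HlLtJ and C57BL/6J were higher in NZO/HlLtJ, against 51.5% with TMM. The median of all genes moved by at most 0.05 under another scaling.

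Diet counts were small and moved with the processing, and the cause was not tested except where fewer samples were fitted. DESeq2 was run without the filter on low counts, with 28507 genes given an adjusted p for diet in NZO/HlLtJ against 22873 by edgeR. Tool, scaling and filter thus changed together there. In C57BL/6J 2 genes became 0 with limma voom, in a fit of the 2 groups alone, with a 2-fold limit and without the libraries with epididymal transcripts. In CAST/EiJ 0 became 3 with DESeq2, 1 with limma voom and 1 on the deposited log2 values. In NZO/HlLtJ 1 became 7 with DESeq2, 2 with no filter, 2 without the libraries with epididymal transcripts, 3 without those apart on the fourth component, and 0 with the run of ID numbers as a covariate, in a fit of the 2 groups alone and with a 2-fold limit. Averaged over strains, 0 became 4 with DESeq2. Over all strains the interaction count of 0 became 7 with DESeq2 and 1 without the NZO/HlLtJ libraries apart. The count was 2 with DESeq2 for NZO/HlLtJ against C57BL/6J, and for NZO/HlLtJ against CAST/EiJ it was 2 without the libraries with epididymal transcripts and 1 without those apart. Without 1 library the counts ran from 0 to 2 in C57BL/6J, 0 to 3 in CAST/EiJ (3 without 44% fat replicate 3), 0 to 5 in NZO/HlLtJ (5 without 10% fat replicate 4), 0 to 2 averaged over strains, 0 to 1 over all interactions, 0 to 1 for NZO/HlLtJ against C57BL/6J, 0 to 0 for CAST/EiJ against C57BL/6J and 0 to 2 for NZO/HlLtJ against CAST/EiJ.

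With an estimated correlation, or by fry, 0 lists were called for diet in any strain, averaged, or in any interaction. For NZO/HlLtJ against C57BL/6J the estimated correlation left 1 list and fry called 27. For NZO/HlLtJ against CAST/EiJ these numbers were 0 and 32, and for CAST/EiJ against C57BL/6J 0 and 17. Without the libraries with epididymal transcripts 3 lists were called for diet in C57BL/6J and 9 for the interaction of NZO/HlLtJ and CAST/EiJ, and without the NZO/HlLtJ libraries apart 10 for the latter. Without 1 library, camera called 2 to 9 lists for diet in C57BL/6J, 5 to 9 in CAST/EiJ, 2 to 13 in NZO/HlLtJ and 5 to 17 averaged. Interactions gave 2 to 13 for NZO/HlLtJ and C57BL/6J, 1 to 7 for CAST/EiJ and C57BL/6J and 1 to 13 for NZO/HlLtJ and CAST/EiJ. Strain comparisons gave 10 to 14 for NZO/HlLtJ and C57BL/6J, 0 to 3 for CAST/EiJ and C57BL/6J and 5 to 9 for NZO/HlLtJ and CAST/EiJ.

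Among named genes, direction changed only for values that did not pass, of which Star in NZO/HlLtJ (-0.32) and Muc5b (-2.61) were not near 0. Muc5b in C57BL/6J was 0.15 without the libraries with epididymal transcripts (-2.97 to 0.15 without 1 library). With limma voom Nnt was 0.01 for diet in C57BL/6J (-0.04 to 0.02 without 1 library) and -0.01 in the interactions of NZO/HlLtJ and C57BL/6J (-0.01 to 0.04), CAST/EiJ and C57BL/6J (-0.02 to 0.04) and NZO/HlLtJ and CAST/EiJ (-0.02 to 0.03). Without 1 library Nnt ran from -0.02 to 0.03 for diet in NZO/HlLtJ and Star from -0.19 to 0.12 for diet in C57BL/6J. Star in NZO/HlLtJ was 0.03 with the run of ID numbers as a covariate (-0.51 to 0.07 without 1 library), and Insl3 averaged over strains 0.01 without the NZO/HlLtJ libraries apart (-0.07 to 0.07 without 1 library). No pairing by replicate was possible because the labels give no replicate numbers, so the run of ID numbers was the only block tried. Depth limits genes at a few counts per library, where folds are given as bounds or ratios.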

Other observations

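No tests of explanations are given in this part, and its genes come from lists that were fixed before the result was seen. Genes of the sex chromosomes that occur in many copies and are active in spermatids differed between strains without a common direction. Of 21 tested, 9 rose and 7 fell in CAST/EiJ against C57BL/6J (median log2 fold change 0.34, mean -0.62, camera direction up, adjusted p = 0.929), and 7 rose and 7 fell in NZO/HlLtJ against C57BL/6J (median 0.09, mean of fitted values -0.26, camera direction down, adjusted p = 0.766). Slxl1, an X-linked gene of this group, stood at 1.51 ± 0.272 CPM in CAST/EiJ (n = 7) against 16.4 ± 1.06 in C57BL/6J and 12.9 ± 1.07 CPM in NZO/HlLtJ (n = 8 each). The X-linked gene Ott was at 0 counts in NZO/HlLtJ against 1.66 ± 0.569 CPM in C57BL/6J, at least 169-fold lower, and weighs on that mean through a fitted value that is no bound. Cypt3 stood at 35.6 ± 3.78 against 56.1 ± 4.80 CPM in the same comparison. Copies of these genes are nearly identical, so the assignment of reads to single members is uncertain.

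Single genes of stress, clock and lipid lists also differed between strains, in no common direction and in lists that camera did not call in the comparisons given. The nuclear receptor gene Rora of the circadian clock stood at 21 ± 1.57 CPM in CAST/EiJ (n = 7) against 46.3 ± 4.19 in C57BL/6J and 44.4 ± 3.27 CPM in NZO/HlLtJ (n = 8 each), and Per2 at 14 ± 0.852 CPM in CAST/EiJ against 8.54 ± 0.456 CPM in NZO/HlLtJ. The heat shock co-chaperone gene Bag3 was at 36.4 ± 2.01 CPM in C57BL/6J, 23.5 ± 2.37 in CAST/EiJ and 21.2 ± 1.40 CPM in NZO/HlLtJ. The adhesion gene Vcam1 was at 72.5 ± 9.41 CPM in C57BL/6J, 164 ± 20.7 in CAST/EiJ and 212 ± 36.3 CPM in NZO/HlLtJ. The heme oxygenase gene Hmox1 was at 16.3 ± 0.953 CPM in CAST/EiJ against 7.68 ± 0.951 CPM in C57BL/6J. Of the lipid synthesis genes, Fasn stood at 235 ± 18.0 against 147 ± 9.26 CPM and Thrsp, which is also on the adipose list, at 6.19 ± 1.12 against 1.07 ± 0.280 CPM in the same comparison.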
